A study of Mus musculus with 32 samples.

How the data were processed

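Liver RNA of 32 male C3H/HeNCrl mice on a high fat diet was sequenced from polyadenylated transcripts with a stranded mRNA kit, per the labels' protocols, and each library was placed in its photoperiod and ZT group from its own labels (8 groups of 4). Per the submitters' processing notes, the tools were bcl2fastq 2.20.0, STAR 2.7.2b and featureCounts 1.6.2 with GRCm38 (mm10). The strand setting, the handling of reads that match several places and the annotation used for counting are not given in the sources used here. The authors deposited a table of whole-number read counts per gene, not normalized, with 55471 genes of which 32791 had a read in any library. The authors also deposited a table of log2 values for 13432 genes, which differed from log2 CPM computed here by at most 0.0213 (median 0.00469), so it was used only as an alternative. Every column of both tables matched the labels of 1 sample. Gene bounds and symbols came from GENCODE M21 on GRCm38, which holds 55230 of the gene identifiers, 14445 of the 14456 tested genes among them.

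Counts were scaled with trimmed mean of M values factors, genes were kept with the filterByExpr function by group, and 14456 genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. A single fit held the means of the 8 groups over all 32 libraries without further covariates, so that all comparisons shared 1 estimate of the spread. Contrasts gave SL minus LL at each ZT and as the mean of the 4 ZTs, the photoperiod by ZT interaction (3 degrees of freedom), time of day within SL and within LL (3 degrees of freedom), and the difference in 24 h rhythm (2 degrees of freedom). With samples 6 h apart, the differences ZT0 minus ZT12 and ZT6 minus ZT18 are the terms of a 24 h cosine wave, from which amplitudes and peak times were computed. A wave with a period other than 24 h, or a sharp peak between sampling times, cannot be told apart from a 24 h wave by 4 times. P-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Log2 CPM used a prior count of 2, and group levels are given as mean CPM with SD. The median amplitude ratio and the median peak shift were tested by redrawing photoperiod labels within ZT 100 times. Redrawn labels mix waves whose peaks differ, which leaves no test of the amplitude, so a jackknife over libraries of the mean log2 amplitude ratio was added after seeing the data. The permutation test of the shift first used a plain median of differences between -18 and 6 h. The circular median replaced it after its p had been seen, and a plain median between -12 and 12 h was added later.

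In total 40 gene lists, pathways of liver metabolism and stress and markers of other cell types and tissues, were fixed before the data were examined, as were the groups, the tests and most alternatives. Lists were tested in 5 comparisons with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 38 lists with at least 2 tested genes and the 5 comparisons (190 tests), with camera at an estimated correlation and with fry beside it. Camera compares a list with all other genes, and fry does not. At the preset correlation camera called 60 of the 190 tests, with the estimated correlation 0, and fry called 45. The named genes followed a rule fixed at the same time. It took the 4 largest rises and falls per ZT among called genes with a mean CPM of at least 1, the 10 smallest p for the interaction and the rhythm, the 10 largest mean amplitudes among named genes called in time of day in both photoperiods, all tested clock genes, and per described list the 2 to 4 members with the smallest p. Unnamed loci were skipped, and a few genes that the rule takes are not reported here, though the counts include them.

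Alternatives were DESeq2 1.42.0 size factors, DESeq2, limma-voom, scaling without mitochondrial and the 20 most abundant genes, no filter and a stricter filter, fits on fewer groups, the replicate number as a block, and each library left out in turn. Added after seeing the data were limma on the authors' log2 values, a set of 4 libraries left out together, LL waves moved in time, and LL taken 6, 12 or 18 h later. The procedure was tested on simulated counts for 14456 genes. A log2 change of 1 at ZT6 was recovered in 84 of 100 changed genes and a change of 2 in 100 of 100, with 10 unchanged genes called. A further 200 genes were given waves 10 h apart with a log2 amplitude of 0.5 in both photoperiods. For these the rhythm difference recovered 188, the interaction 186, time of day in SL 160 and in LL 158, with a median estimated shift of -10.04 h. Real genes called in both photoperiods had median amplitudes of 0.36 in SL and 0.34 in LL, and recovery of such weaker waves was not simulated.

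Total counts of 9095615 to 27462776 per library set the precision, so a gene at 1 CPM rests on few reads per library. Libraries of one group were compared in 48 pairs, and none agreed within counting noise (chi-square per degree of freedom 6.19 to 136), so no library was treated as a copy. Mitochondrially encoded genes took 3.05% to 4.31% of the counts. Among them mt-Co1 had 8915102 reads over all libraries while mt-Co2 had 53 and mt-Atp6 53, so the counts of the mitochondrial genes do not reflect transcript levels evenly. Genes whose reads can be shared with near-identical copies (the Mup family, Cyp2a4 and Cyp2a5, Hspa1a and Hspa1b, Acot1 and Acot3) and 37 of the 258 named genes that overlap another tested gene are uncertain, because the counting rules are not known here.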

Results

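Livers of 32 male C3H/HeNCrl mice, an inbred strain that makes melatonin, were profiled by polyadenylated RNA sequencing after feeding on a high fat diet. The mice lived under short light (SL) or long light (LL), 16 mice each, and were sampled at zeitgeber time (ZT, hours counted on the light schedule) 0, 6, 12 and 18. Each of the 8 groups held 4 mice, so n = 4 per group throughout. The labels give every library as a separate mouse, so p-values measure the spread between mice. The hours of light per day in SL and LL, and the event that sets ZT0, are not given in the sources used here. Total counts ranged from 9095615 to 27462776 reads per library (median 15665632), and between 19641 and 22755 genes had at least 1 read. Of 55471 annotated genes, 14456 were tested. Mean correlation of log2 CPM (read counts scaled to library size) with group mates lay between 0.981 and 0.989 for all libraries except LL ZT12 replicate 3, at 0.969. On the first principal component, which held 16.7% of the variance, SL ZT0 and SL ZT6 lay on the same side as LL ZT12 and LL ZT18, and the other 4 groups lay on the opposite side.

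**Figure D1:**
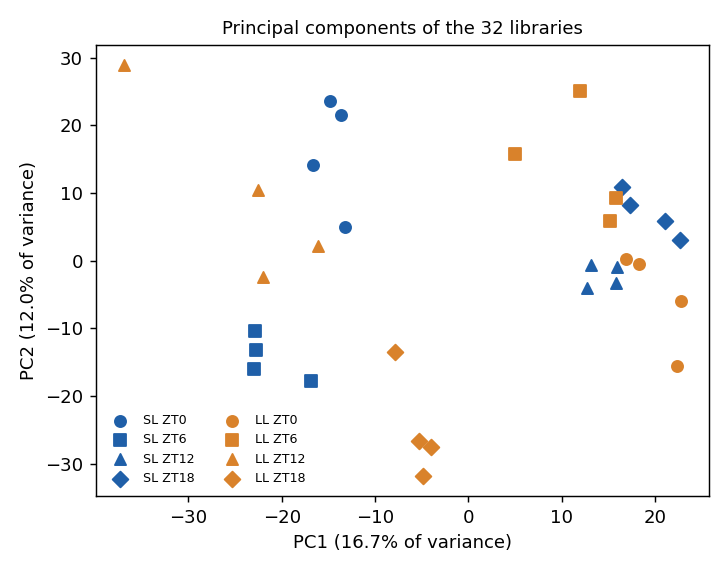
Scores of the 32 libraries on the first principal component (x axis, 16.7% of the variance) and the second (y axis, 12.0%) of log2 CPM, 1 point per library, coloured by photoperiod and shaped by ZT. SL ZT0 and SL ZT6 share the left side with LL ZT12 and LL ZT18, and the highest point at the far left is LL ZT12 replicate 3.

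The first question was which transcripts varied with time of day within each photoperiod. In SL, Arntl (Bmal1), which codes for the activator that pairs with CLOCK or NPAS2 in the clock loop, was lowest at ZT0 (2.45 ± 0.70 CPM, SD, n = 4) and highest at ZT12 (38.7 ± 1.98 CPM). In LL the same transcript was highest at ZT0 (39.3 ± 2.55 CPM) and lowest at ZT12 (3.36 ± 1.41 CPM). Dbp, which codes for a clock-driven activator of liver enzymes, stood at 109 ± 22.3 CPM at ZT0 and 2.88 ± 0.68 CPM at ZT12 in SL, against 2.24 ± 0.59 and 95.2 ± 50.8 CPM in LL. Nr1d1, which codes for the haem-binding repressor REV-ERB alpha, peaked at ZT0 in SL (98.8 ± 24.1 CPM) and at ZT6 in LL (87.1 ± 18.2 CPM). Of the 19 core clock and clock output genes, 18 varied with time of day in SL and 18 in LL, the same counts when adjusted over the list alone. The exception in both was Rora, with edgeR adjusted p = 0.908 in SL and 0.460 in LL.

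The waves of these genes were large. The log2 amplitude of a fitted 24 h wave was 3.91 for Npas2 in SL and 3.14 in LL (SE 0.25), 2.73 and 2.83 for Dbp, 2.98 and 2.28 for Ciart, 2.57 and 2.2 for Nr1d1, 2.15 and 1.99 for Per3, and 2.08 and 1.83 for Arntl (SE 0.15). Npas2 stood at 0 CPM in SL ZT6 replicates 3 and 4 and in LL ZT12 replicate 1. Its amplitudes, and their difference between SL and LL, therefore depend on the prior count of 2. Lower amplitudes were fitted for other clock genes, among them Bhlhe41 (1.91 and 0.99), Per1 (1.65 and 1.59), Nr1d2 (1.57 and 1.29), Cry1 (1.29 and 1.09), Tef (1.2 and 1.13), Nfil3 (0.77 and 0.60), Bhlhe40 (0.73 and 0.52), Per2 (0.69 and 0.79), Clock (0.58 and 0.81), Hlf (0.39 and 0.31) and Cry2 (0.34 and 0.31). Among genes called in time of day in both photoperiods, unnamed loci aside, the 10 largest mean amplitudes belonged to Npas2, Dbp, Ciart, Usp2, Nr1d1, Pitx3, Per3, Acot3, Arntl and Elovl3. Usp2, a deubiquitinase gene, had amplitudes of 2.66 and 2.41 (SE 0.16), and Elovl3, a fatty acid elongase gene, 1.97 and 1.77 (SE 0.12). Acot3, whose reads can be shared with Acot1, had amplitudes of 2.03 and 1.89 (SE 0.31). Pitx3 had 2.31 and 2.24 (SE 0.23) at a mean of only 2.11 CPM. It ends 10 bases inside Elovl3 on the opposite strand, and its wave followed that of Elovl3, so its reads are uncertain.

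On GRCm38, with GENCODE M21 gene bounds, Arntl (ENSMUSG00000055116) lies on chromosome 7 from 113207465 to 113314126 and Npas2 (ENSMUSG00000026077) on chromosome 1 from 39193731 to 39363236. Dbp (ENSMUSG00000059824) spans chromosome 7 from 45705088 to 45710203 and overlaps Sphk2 by 737 bases, and Nr1d1 (ENSMUSG00000020889) spans chromosome 11 from 98767932 to 98775333 and overlaps Thra by 1075 bases, both on opposite strands. Per3 lies on chromosome 4 from 151003652 to 151044665, inside the bounds of Camta1 on the same strand. Ciart lies on chromosome 3 from 95878503 to 95882251, Usp2 (ENSMUSG00000032010) on chromosome 9 from 44067021 to 44095627, Elovl3 (ENSMUSG00000038754) on chromosome 19 from 46131897 to 46135694, Pitx3 next to it from 46135685 to 46148326, and Acot3 on chromosome 12 from 84052144 to 84060402. All are protein-coding genes, and the counts cover their annotated exons as a whole.

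**Figure D2:**
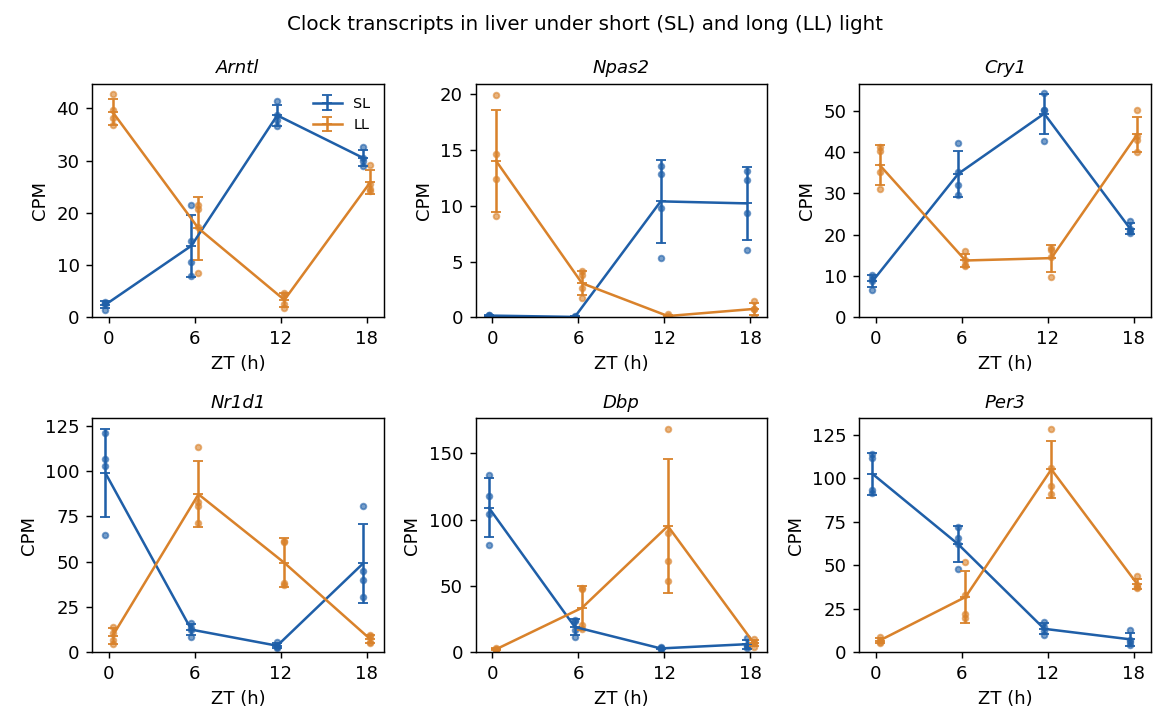
CPM (y axis) of Arntl, Npas2, Cry1, Nr1d1, Dbp and Per3 against ZT in hours (x axis) in SL and LL liver, with points for single mice, lines through the group means and bars for 1 SD (n = 4). Arntl in SL is lowest at ZT0 (2.45 CPM) while in LL it is lowest at ZT12 (3.36 CPM).

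Across all tested genes, time of day passed an adjusted p of 0.05 in 2756 genes in SL (19.1%) and 2650 in LL (18.3%), and 1752 genes passed in both, against 505 if the calls had been independent. Cholesterol synthesis and uptake had 18 of 25 genes called in SL and 18 in LL (20 and 20 adjusted over the list alone), heat shock proteins 16 and 15 of 18 (16 and 16 alone), ER chaperones 15 and 13 of 17 (15 and 15 alone), amino acid and urea metabolism 11 and 15 of 20 (11 and 15 alone), and fatty acid and triglyceride synthesis 11 and 11 of 20 (13 and 12 alone). Fatty acid oxidation had 13 and 9 of 26 called (17 and 11 alone), bile acid synthesis and transport 12 and 8 of 19 (12 and 12 alone), gluconeogenesis 11 and 9 of 16 (15 and 11 alone), and xenobiotic metabolism 10 and 10 of 23 (15 and 12 alone). None of the 24 ribosomal protein genes, 12 Kupffer cell and macrophage markers or 7 mitochondrially encoded transcripts was called by edgeR in either photoperiod, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 they had 0, 0 and 1 genes in SL and 0, 7 and 0 in LL. The 7 skeletal muscle markers were called in LL (7 of 7) and not in SL (0 of 7, 3 alone). Their mean level was 10.8 ± 12.7 CPM in LL ZT18 and 3.81 ± 6.75 CPM in LL ZT0, with an SD as large as the mean, and the photoperiod by ZT interaction called 0 of the 7. Fitted on the 16 libraries of each photoperiod alone, the counts were 3508 in SL and 1655 in LL, so their near-equality depends on the shared fit.

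The next question was whether the daily rhythm differed between SL and LL. Peaks came about 10 h earlier on the ZT scale in SL, or later by the rest of the 24 h cycle, which fitted waves cannot tell apart. Arntl peaked at 13.2 h in SL and 23.3 h in LL, a shift of -10.1 h, and Per1 at 3.27 and 14.5 h, a shift of -11.2 h. Nr1d1 peaked at 22.6 and 8.34 h (-9.79 h), Dbp at 1.22 and 10.5 h (-9.29 h), and Cry1, which codes for a late repressor of the loop, at 11 and 20.6 h (-9.64 h). Among other clock genes called in both photoperiods the shift was -10.1 h for Npas2, -9.69 h for Clock, -9.17 h for Per2, -9.27 h for Per3, -10.5 h for Cry2, -9.81 h for Nr1d2, -9.93 h for Tef, -10.7 h for Hlf, -9.60 h for Nfil3, -10.0 h for Ciart, -10.7 h for Bhlhe40 and -10.6 h for Bhlhe41. The list median was -9.87 h over 18 genes, and the mean was -9.97 h with a jackknife SE over libraries of 0.312 h.

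A different 24 h rhythm was called in 5205 genes (36.0%), among them 1749 of the 1752 genes that varied with time of day in both photoperiods. The 10 genes with the smallest p included Por, Usp2, Ppard, Upp2, Cry1, Tef, Nrg4 and Elovl3, for which the shift was -9.74 h in Por, -10.6 h in Usp2, -9.17 h in Ppard, -10.5 h in Upp2, -10.1 h in Nrg4 and -9.95 h in Elovl3. In the 1752 genes the median shift was -10.1 h (interquartile range -10.8 to -9.39 h), and 1584 of them (90.4%) lay within 2 h of it. In the mean of both photoperiods, waves about 10 h apart largely cancel, so the 194 genes called on it are those that cancel least. Their shift and amplitude ratio need not stand for those of all genes. Over the 194 genes chosen on the mean of both photoperiods, the median shift was -9.54 h (permutation p = 0.02, two-sided, 100 draws of photoperiod labels within ZT). That p belongs to a circular median, which was taken up only after a plain median of differences between -18 and 6 h had given a permutation p of 0.06. With the 1752 genes in place of the 194, permutation p was 0.05.

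**Figure D3:**
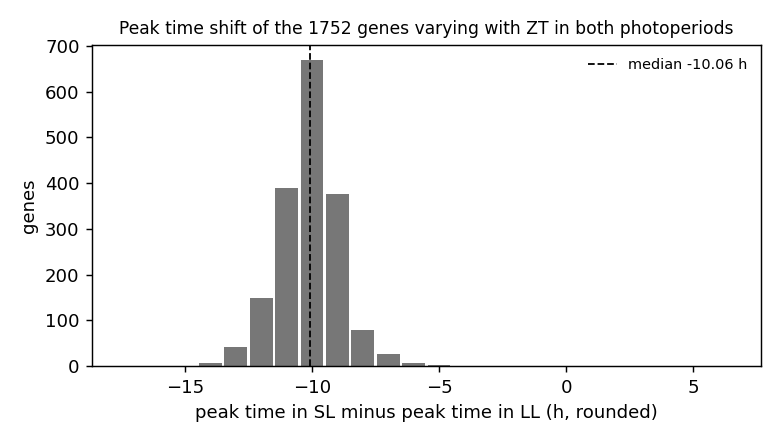
Number of genes (y axis) by the difference in fitted peak time, SL minus LL, rounded to whole hours (x axis), for the 1752 genes that varied with ZT in both photoperiods. The dashed line marks the median of -10.06 h.

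Amplitudes were compared over the same genes. The median amplitude of the 1752 genes was 0.36 in SL and 0.34 in LL on the log2 scale, and 985 of them had the higher value in SL. Over the 194 genes the median ratio of SL to LL amplitude was 1.03 (permutation p = 0.86). Redrawn labels mix SL and LL waves about 10 h apart, so that p does not test the amplitude. By a jackknife over libraries, chosen after seeing the data, the mean log2 ratio was -0.000448 over the 194 genes (SE 0.0918), 0.0412 over the 1752 genes (SE 0.0746) and 0.196 over the core clock list (SE 0.09, 2.17 SE from 0), in which 15 of 18 genes had the higher amplitude in SL. The clock list was the 1 of 15 lists beyond 2 SE, with no correction for their number.

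The photoperiod by ZT interaction, which asks whether the SL minus LL difference changed over the day without assuming a wave, was called in 4720 genes (32.7%), 4546 of them shared with the rhythm difference. Por, which codes for the reductase that supplies electrons to liver cytochrome P450 enzymes, stood at 530 ± 86.8 CPM in SL and 94.9 ± 26 CPM in LL at ZT6, and at 61.9 ± 12.2 and 355 ± 37.8 CPM at ZT18, with no overlap between the 4 mice of each group at either time. Its edgeR adjusted p was 1.87e-15, as it was for Usp2, Ppard, Upp2, Cry1 and Tef, followed by Nrg4 (2.61e-15) and Elovl3 (4.41e-15). Ppard codes for a lipid-sensing nuclear receptor, Upp2 for a uridine phosphorylase and Nrg4 for a secreted growth factor. Elovl3 stood at 573 ± 108 CPM in SL ZT12 and 49.1 ± 8.72 CPM in LL ZT12. Por (ENSMUSG00000005514) lies on chromosome 5 from 135670033 to 135735326, Ppard on chromosome 17 from 28232700 to 28301474, Upp2 on chromosome 2 from 58567298 to 58792971, Cry1 on chromosome 10 from 85131700 to 85185064, and Nrg4, which overlaps Fbxo22 on the opposite strand, on chromosome 9 from 55220222 to 55326844.

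Most members of many metabolic lists entered that count. The interaction was called in 18 of 19 clock genes (18 adjusted over the list alone), 21 of 25 cholesterol genes (22 alone), 17 of 18 heat shock protein genes (17 alone), 15 of 17 ER chaperone genes (16 alone), 15 of 16 genes of glucose uptake, glycolysis and glycogen (15 alone), 14 of 16 gluconeogenesis genes (14 alone), 16 of 20 amino acid genes (16 alone), 14 of 20 fatty acid synthesis genes (15 alone), 14 of 19 bile acid genes (16 alone), 16 of 26 fatty acid oxidation genes (19 alone), 13 of 23 xenobiotic genes (13 alone) and 13 of 18 interferon response genes (14 alone). It was called by edgeR in 0 of 24 ribosomal protein genes, 0 of 12 Kupffer cell markers, 0 of 11 stellate cell and fibroblast markers and 0 of 7 mitochondrially encoded transcripts, also when adjusted over the list alone, with 0, 5, 1 and 1 at an unadjusted p under 0.05. When SL was compared with LL sampled 12 h later on the cycle, the count of genes with an interaction was 75, with LL sampled 6 h later it was 1350, and with LL sampled 18 h later 3821. These comparisons were chosen after seeing the data.

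The remaining comparisons set SL against LL at a single ZT each, with log2 fold changes given as SL minus LL with their SE (n = 4 per group). Since peak times differed between the photoperiods, a shift in time alone can give differences at a single ZT, also in whole lists. These comparisons do not separate such a shift from a change in level. At ZT0 most clock genes differed, some higher and some lower in SL. Dbp was higher by 5.65 ± 0.44, Ciart by 4.86 ± 0.50, Bhlhe41 by 4.01 ± 0.48 and Per3 by 3.95 ± 0.27, the 4 largest rises. The 4 largest falls were in Npas2 (-6.16 ± 0.53), Pitx3 (-4.52 ± 0.58), Arntl (-3.97 ± 0.29) and Cdkn1a (-3.60 ± 0.31), the last a cell cycle inhibitor gene. Of the 19 clock genes, 18 changed (18 adjusted over the list alone). The 12 that rose also held Nr1d1 (3.45), Nr1d2 (2.55), Per1 (2.29), Tef (2.21), Per2 (1.18), Bhlhe40 (1.07), Cry2 (0.75) and Hlf (0.62), and the 6 that fell also held Cry1 (-2.07), Clock (-1.47) and Nfil3 (-1.46). Rora was at -0.23 ± 0.20 and was not called. Camera placed the clock list higher at adjusted p = 0.000858, and at adjusted p = 0.125 with an estimated correlation.

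At ZT0 more genes were higher than lower in SL in both lists of lipid synthesis. Of 20 fatty acid and triglyceride synthesis genes, 12 rose and 0 fell (14 adjusted over the list alone). The smallest p belonged to Thrsp, a lipogenic regulator (1.65 ± 0.23), Srebf1, which codes for the transcription factor SREBP1 (1.01 ± 0.16), Dgat2 (0.49 ± 0.08) and Acss2 (0.81 ± 0.14). Camera placed the list above other genes at adjusted p = 3.57e-08, and at adjusted p = 0.275 with an estimated correlation. Of 25 cholesterol synthesis and uptake genes, 15 rose and 0 fell (18 alone). Among them were Nsdhl (0.66 ± 0.10), Hsd17b7 (0.75 ± 0.14) and Msmo1 (0.69 ± 0.14), with camera adjusted p = 2.19e-09 and adjusted p = 0.357 with an estimated correlation. In gluconeogenesis and the fasting response, 6 of 16 genes rose and Igfbp1 fell (10 called alone), with Sds at 1.42 ± 0.19, Klf15 at 0.86 ± 0.12 and Igfbp1 at -2.26 ± 0.53. Its camera adjusted p was 0.00144, and adjusted p = 0.255 with an estimated correlation. Abcg8 (0.88 ± 0.12) and Abcg5 (0.80 ± 0.12), overlapping genes for the partners of a sterol exporter, rose in the bile acid list, in which 4 of 19 genes rose and 1 fell (9 called alone), with camera adjusted p = 0.472. In glucose uptake, glycolysis and glycogen, 5 of 16 rose and 1 fell (8 alone), with the glycogen synthase gene Gys2 at 1.10 ± 0.11 and Ppp1r3c at -1.77 ± 0.24, and camera adjusted p = 0.0610.

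Other lists moved in either direction at ZT0. Among 18 heat shock protein genes, Hspb1 (-1.51 ± 0.24), Hsp90aa1 (-0.74 ± 0.18) and Hspa4l (-0.63 ± 0.16) fell and 0 rose (4 alone), with camera adjusted p = 0.00199 and adjusted p = 0.595 with an estimated correlation. Of 22 acute phase genes, 5 fell and 0 rose (5 alone), namely the C-reactive protein gene Crp (-0.46 ± 0.08), the fibrinogen genes Fgg, Fga and Fgb (-0.58, -0.57 and -0.46) and Itih3 (-0.44), with camera adjusted p = 0.00135 and adjusted p = 0.595 with an estimated correlation. The interferon response genes Usp18 (0.92 ± 0.20), Isg15 (0.82 ± 0.20), Zbp1 (1.29 ± 0.32) and Irf7 (0.59 ± 0.18) rose out of 18 (6 alone), with camera adjusted p = 0.0255 and adjusted p = 0.883 with an estimated correlation. Wee1, a cell cycle kinase gene, rose by 2.24 ± 0.22, with Ccne1, Ccnd1 and Mcm5 the 4 of 19 cell cycle genes that rose (4 alone), with camera adjusted p = 0.25. Sox9 fell by 1.83 on the log2 scale as the only called gene of 6 cholangiocyte markers (1 alone), a list that camera placed lower at adjusted p = 0.0160, and adjusted p = 0.255 with an estimated correlation. The 7 mitochondrially encoded transcripts were placed lower by camera at adjusted p = 0.0488, and adjusted p = 0.710 with an estimated correlation, with 0 called by edgeR (1 alone). In total 1596 genes differed at ZT0, 878 higher and 718 lower in SL, with a median absolute log2 fold change of 0.57.

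At ZT6 the largest rises were in Usp2 (4.01 ± 0.30), Cyp2a4 (3.97 ± 0.92), Mt2 (3.37 ± 0.72), which codes for a metal-binding protein, and Lmod2 (3.34 ± 0.41), and the largest falls in Npas2 (-5.97 ± 0.71), Gpr179 (-3.75 ± 1.2), Nr1d1 (-2.81 ± 0.30) and Atp2b2 (-2.55 ± 0.45). Npas2 lay at 0 to 0.131 CPM in SL ZT6, at most 0.267 CPM in SL ZT0 and at most 0.316 CPM in LL ZT12. The size of its fold changes at these ZTs therefore rests on few reads. Cyp2a4 shares near-identical sequence with Cyp2a5 and its reads are uncertain. Gpr179 varied widely between mice of one group, at 70.8 ± 83.4 CPM in LL ZT6 and 102 ± 128 CPM in LL ZT12. Of 19 clock genes, 9 rose and 2 fell (13 called adjusted over the list alone), with risers that included Per1 (2.65), Ciart (2.54), Cry1 (1.34), Per3 (0.98), Tef (0.80), Per2 (0.77), Hlf (0.49) and Cry2 (0.31). Bhlhe40 (0.75), Rora (0.27), Nr1d2 (0.08), Clock (0.01), Nfil3 (-0.02), Arntl (-0.32), Bhlhe41 (-0.54) and Dbp (-0.81) were not called. The clock list had a camera adjusted p of 0.00238 (higher), and adjusted p = 0.209 with an estimated correlation.

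Fatty acid oxidation and ketogenesis had 12 of 26 genes higher and 0 lower (16 alone). Among them were the lipase inhibitor gene Angptl4 (1.86 ± 0.20), Acot1 (2.68 ± 0.33, with reads that can be shared with Acot3), and the carnitine carrier gene Slc25a20 (0.54 ± 0.08). Camera gave adjusted p = 1.42e-07, and adjusted p = 0.420 with an estimated correlation. Lipid droplet genes had 6 of 18 higher and 1 lower (8 alone), among them Fitm2 (1.10 ± 0.13), Plin5 (0.96 ± 0.14), Cidec (1.71 ± 0.29) and Plin4 (1.5 ± 0.26), with camera adjusted p = 0.00163 and adjusted p = 0.406 with an estimated correlation. Gluconeogenesis had 8 of 16 higher and 0 lower (10 alone), with Foxo1 at 1.11 ± 0.14 and Gpt2 at 0.64 ± 0.09, camera adjusted p = 2.94e-06, and adjusted p = 0.0806 with an estimated correlation. Xenobiotic metabolism had 8 of 23 higher and 1 lower (11 alone). Por was at 2.48 ± 0.18 and the genes of the receptors PXR and CAR, Nr1i2 (1.09 ± 0.09) and Nr1i3 (1.05 ± 0.16), camera adjusted p = 7.54e-05, and adjusted p = 0.0806 with an estimated correlation. Of 12 glucocorticoid-responsive genes, 7 rose and 0 fell (7 alone). Fkbp5 was at 2.34 ± 0.25, Zbtb16 at 2.75 ± 0.32, Tsc22d3 at 1.30 ± 0.19 and Mt1 at 3.07 ± 0.51, camera adjusted p = 5.27e-07, and adjusted p = 0.0806 with an estimated correlation. Heat shock proteins had 9 of 18 higher and 0 lower (9 alone), including Hspa8 (0.76 ± 0.14) and the near-identical pair Hspa1a and Hspa1b (2.78 ± 0.48 and 1.90 ± 0.31), with camera adjusted p = 1.26e-05 and adjusted p = 0.405 with an estimated correlation. In amino acid and urea metabolism 9 of 20 rose and 3 fell (12 alone), with Asl at 0.98 ± 0.11 and Cbs at -0.92 ± 0.09, camera adjusted p = 0.000578, and adjusted p = 0.497 with an estimated correlation.

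In some other lists more genes were lower than higher at ZT6. Of 17 ER chaperone genes, 13 fell and 1 rose (14 alone). Calr, which codes for the calcium-binding chaperone calreticulin, was at -0.95 ± 0.11, Pdia6 at -0.66 ± 0.08, Manf at -1.38 ± 0.18 and Pdia4 at -0.85 ± 0.11, camera adjusted p = 9.59e-11, and adjusted p = 0.275 with an estimated correlation. In the integrated stress response, Atf5 (-0.88 ± 0.11), Nupr1 (-1.48 ± 0.30), Atf4 (-0.59) and Psat1 (-1.15) fell out of 12 (4 alone), with camera adjusted p = 0.0383 and adjusted p = 0.452 with an estimated correlation. Interferon response genes fell in 10 of 18 cases and rose in 0 (10 alone). Oasl1 was at -1.08 ± 0.15, Ddx58 at -0.69 ± 0.10 and Isg15 at -1.18 ± 0.20, camera adjusted p = 3.37e-06, and adjusted p = 0.497 with an estimated correlation. Cholesterol synthesis fell in 9 of 25 genes and rose in 0 (12 alone). Hmgcs1 was at -1.41 ± 0.20, Mvd at -1.55 ± 0.26, Fdft1 at -0.65 ± 0.12 and Sc5d at -0.63 ± 0.12, camera adjusted p = 5.94e-05, and adjusted p = 0.595 with an estimated correlation. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, rose by 1.71 ± 0.33, and the bile salt pump gene Abcb11 was at -0.88 ± 0.11, in a list with 2 of 19 higher and 3 lower (7 alone) and camera adjusted p = 0.940. Camera also placed nuclear-encoded oxidative phosphorylation (4 of 24 higher, 4 alone; adjusted p = 0.000175), cell cycle (3 of 19 higher, 4 alone; 0.0283) and periportal hepatocyte genes (4 of 12 higher and 1 lower, 6 alone; 0.0380) above other genes, with adjusted p = 0.626, 0.814 and 0.456 with an estimated correlation. Fatty acid and triglyceride synthesis had 6 of 20 higher, Lpin1 by 2.44 ± 0.27, and 2 lower (10 alone), with camera adjusted p = 0.0991, and acute phase genes 3 of 22 higher and 5 lower (9 alone), with camera adjusted p = 0.336. In total 2208 genes differed, 997 higher and 1211 lower in SL, with a median absolute log2 fold change of 0.55. The majority turned without LL ZT12 replicate 3 (1567 higher, 1486 lower), without a filter on low counts (944 and 873) and without 4 libraries chosen after seeing the data (1583 and 1500).

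**Figure D4:**
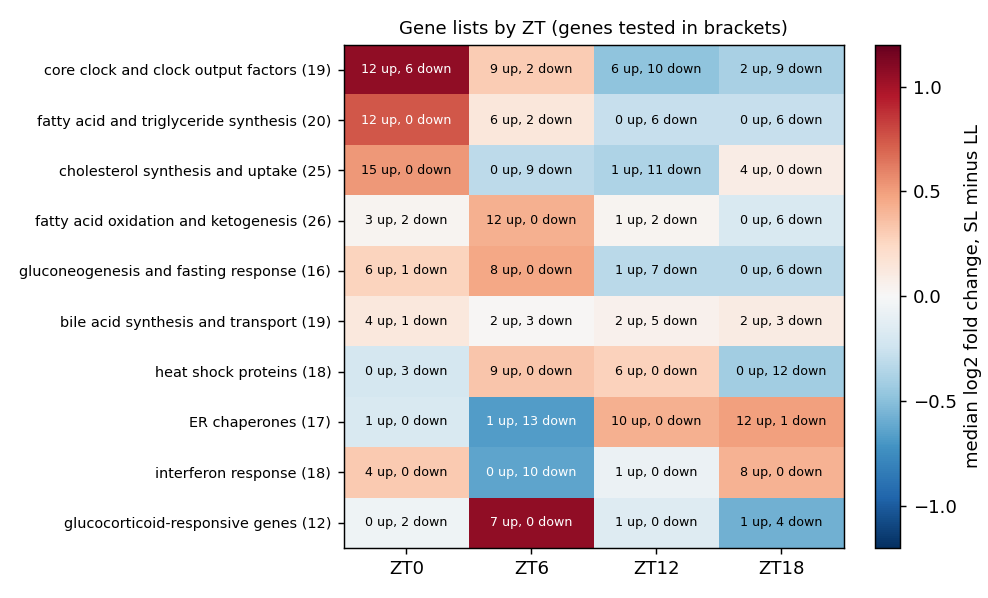
Median log2 fold change, SL minus LL (colour scale), of 10 gene lists (vertical axis, genes tested in brackets) at each ZT (horizontal axis), with the number of genes called higher (up) and lower (down) in SL printed in each cell. ER chaperones, for example, have 13 of 17 genes lower at ZT6 and 12 of 17 higher at ZT18.

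At ZT12 the clock genes called had the opposite sign to ZT0. Npas2 was higher in SL by 6.18 ± 0.52, Pitx3 by 5.87 ± 0.64, the phosphate carrier gene Slc34a2 by 4.02 ± 0.60 and Elovl3 by 3.54 ± 0.24. The largest falls were in Dbp (-5.04 ± 0.42), Ciart (-4.73 ± 0.49), Nr1d1 (-3.78 ± 0.35) and Ppp1r3g (-3.30 ± 0.64), a glycogen-targeting subunit gene. Of 19 clock genes, 6 rose and 10 fell (17 called adjusted over the list alone). Arntl (3.52), Cry1 (1.78), Clock (1.12) and Nfil3 (1.11) were among those that rose with Npas2, and Per3 (-2.97), Nr1d2 (-2.91), Bhlhe41 (-2.71), Per1 (-2.40), Tef (-1.75), Per2 (-0.69) and Hlf (-0.48) were among those that fell. Cry2 (-0.21), Bhlhe40 (-0.40) and Rora (0.24) were not called. For the clock list camera gave adjusted p = 0.0130 (lower), and adjusted p = 0.302 with an estimated correlation.

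Several metabolic lists had more genes lower than higher in SL at ZT12, while lipid droplet genes (3 of 18 higher and 2 lower, 6 alone) and amino acid and urea metabolism (3 of 20 higher and 2 lower, 6 alone) did not. Cholesterol synthesis fell in 11 of 25 genes and rose in 1 (15 alone). Msmo1 was at -0.99 ± 0.14 and Nsdhl at -0.76 ± 0.10, camera adjusted p = 8.32e-06, and adjusted p = 0.517 with an estimated correlation. Fatty acid and triglyceride synthesis fell in 6 of 20 and rose in 0 (7 alone). Thrsp was at -1.36 ± 0.23, Acss2 at -0.70 ± 0.14 and Fads2 at -0.68 ± 0.14, camera adjusted p = 0.00741, and adjusted p = 0.663 with an estimated correlation. Gluconeogenesis fell in 7 of 16 and rose in 1 (11 alone). Sds was at -1.87 ± 0.20, the rate-controlling enzyme gene Pck1 at -1.31 ± 0.23 and Irs2 at 1.27 ± 0.29, camera adjusted p = 0.00166, and adjusted p = 0.255 with an estimated correlation. Xenobiotic metabolism fell in 8 of 23 and rose in 0 (10 alone), with Por at -1.63 ± 0.17, camera adjusted p = 0.000578, and adjusted p = 0.125 with an estimated correlation. Bile acid genes fell in 5 of 19 and rose in 2 (11 alone), with Cyp7a1 at -1.71 ± 0.33, Abcg5 at -0.96 ± 0.12 and Abcg8 at -0.87 ± 0.12, and camera adjusted p = 0.584. Pericentral hepatocyte genes fell in 5 of 12 and rose in 0 (5 alone), namely Lhpp, Cyp1a2, Oat, Cyp2e1 and Slc1a2, with camera adjusted p = 0.0155 and adjusted p = 0.640 with an estimated correlation.

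At ZT12 some chaperone genes, endothelial markers and 1 Kupffer cell marker were higher in SL, while no stellate cell (0 of 11), T and NK cell (0 of 3), B and plasma cell (0 of 5) or neutrophil marker (0 of 2) was called by edgeR (0 alone). ER chaperones rose in 10 of 17 and fell in 0 (12 alone). Pdia4 was at 0.72 ± 0.11, Creld2 at 1.15 ± 0.18, Hyou1 at 1.23 ± 0.20 and Hspa5, which codes for BiP, at 0.92 ± 0.15, camera adjusted p = 3.52e-06, and adjusted p = 0.497 with an estimated correlation. Heat shock proteins rose in 6 of 18 and fell in 0 (9 alone), with Hspb1 at 1.69 ± 0.21, camera adjusted p = 0.000548, and adjusted p = 0.507 with an estimated correlation. Acute phase genes rose in 5 of 22 (5 alone; Crp, Fga, Fgg, Fgb and Itih3), with Crp at 0.45 ± 0.08, Fga at 0.66 ± 0.12 and camera adjusted p = 0.164, so camera did not call the list. The endothelial markers Stab2 (0.41 ± 0.09), Cdh5 (0.59 ± 0.13), Oit3 (0.34 ± 0.10) and Lyve1 (0.74 ± 0.25) rose out of 11 (7 alone), with camera adjusted p = 0.00264 and adjusted p = 0.497 with an estimated correlation, and Clec4f (0.40 ± 0.13) was the 1 of 12 Kupffer cell markers called (6 alone), with camera adjusted p = 0.00393 and adjusted p = 0.657 with an estimated correlation. LL ZT12 replicate 3, the library least like its group, differed from its 3 mates by a median log2 of -0.43 over the endothelial markers and 0.03 over the Kupffer markers. Rpl32 (-0.43 ± 0.14) was the only called ribosomal protein gene of 24 (0 alone), with camera adjusted p = 0.0391 and adjusted p = 0.943 with an estimated correlation. In total 1799 genes differed, 874 higher and 925 lower in SL, with a median absolute log2 fold change of 0.53, and a fit on the 8 libraries of ZT12 alone called 723. The majority turned with limma-voom (935 higher, 806 lower) and on the authors' log2 values (953 and 813; chosen after seeing the data), and without single libraries such as SL ZT12 replicate 3 (694 and 634).

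At ZT18 Npas2 was higher in SL by 3.73 ± 0.41, Nr1d1 by 2.77 ± 0.32, the prostaglandin D synthase gene Ptgds by 2.57 ± 0.40 and Mup11, one of the near-identical major urinary protein genes, by 2.38 ± 0.49. The largest falls were in Myh4 (-4.39 ± 1.08), Lmod2 (-3.99 ± 0.45), Usp2 (-3.82 ± 0.32) and Tcap (-3.19 ± 0.94). Myh4 and Tcap are skeletal muscle genes, and Myh4 stood at 5.97 ± 6.24 CPM in LL ZT18 and 0.28 ± 0.32 CPM in SL ZT18. Acta1, the actin gene of skeletal muscle, stood at 23.4 ± 28.2 CPM in LL ZT18, 4.64 ± 5.50 CPM in SL ZT18 and 7.73 ± 14.3 CPM in LL ZT0. Of 7 skeletal muscle markers only Myh4 was called (4 alone), with camera adjusted p = 0.00193 and adjusted p = 0.608 with an estimated correlation. Of 19 clock genes, 2 rose and 9 fell (12 called alone), with genes that included Per3 (-2.38), Ciart (-1.89), Per1 (-1.80), Bhlhe40 (-1.29), Tef (-1.28), Per2 (-1.22), Cry1 (-1.04) and Cry2 (-0.57) lower. Arntl (0.24), Clock (0.22), Nfil3 (0.09), Rora (-0.06), Nr1d2 (-0.07), Dbp (-0.20), Bhlhe41 (-0.37) and Hlf (-0.39) were not called. Camera placed the clock list lower at adjusted p = 7.53e-06, and adjusted p = 0.0806 with an estimated correlation.

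Heat shock proteins fell in 12 of 18 genes at ZT18 and rose in 0 (15 alone). Hspa8 was at -1.06 ± 0.14, Hspa1a at -2.84 ± 0.47 and Hspa1b at -1.78 ± 0.30, camera adjusted p = 8.35e-11, and adjusted p = 0.125 with an estimated correlation. ER chaperones rose in 12 of 17 and fell in 1 (13 alone). Calr was at 0.70 ± 0.11, Pdia6 at 0.53 ± 0.08 and Manf at 1.0 ± 0.18, camera adjusted p = 3.57e-08, and adjusted p = 0.383 with an estimated correlation. Interferon response genes rose in 8 of 18 and fell in 0 (8 alone). Ddx58 was at 0.53 ± 0.10 and Oasl1 at 0.78 ± 0.15, camera adjusted p = 0.000113, and adjusted p = 0.595 with an estimated correlation. Fatty acid and triglyceride synthesis fell in 6 of 20 and rose in 0 (8 alone). Thrsp was at -1.67 ± 0.23, Lpin1 at -1.85 ± 0.27 and Acacb at -1.10 ± 0.23, camera adjusted p = 4.74e-05, and adjusted p = 0.456 with an estimated correlation. Fatty acid oxidation fell in 6 of 26 and rose in 0 (10 alone). Angptl4 was at -1.15 ± 0.20, with camera adjusted p = 0.00135, and adjusted p = 0.663 with an estimated correlation. Amino acid and urea metabolism fell in 7 of 20 and rose in 1 (13 alone), with camera adjusted p = 9.81e-05, and adjusted p = 0.430 with an estimated correlation. Xenobiotic metabolism fell in 6 of 23 and rose in 1 (9 alone), with Por at -2.52 ± 0.18, camera adjusted p = 7.03e-05, and adjusted p = 0.0806 with an estimated correlation. Gluconeogenesis fell in 6 of 16 and rose in 0 (6 alone), and glucose uptake, glycolysis and glycogen fell in 5 of 16 and rose in 1 (10 alone), with camera adjusted p = 0.000193 and 0.00135, and adjusted p = 0.125 and 0.294 with an estimated correlation.

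Glucocorticoid-responsive genes had Fkbp5 (-2.01 ± 0.25), Zbtb16 (-1.40), Mt1 (-2.09) and Mt2 (-2.33) lower and Sgk1 (1.21 ± 0.23) higher out of 12 at ZT18 (6 alone), with camera adjusted p = 0.00199 and adjusted p = 0.304 with an estimated correlation. The immediate early genes Ier3 (-1.55 ± 0.35), Myc (-2.30 ± 0.52) and Fos (-2.12 ± 0.64) fell out of 12 (5 alone), with camera adjusted p = 0.0149 and adjusted p = 0.507 with an estimated correlation. The cholesterol genes Hmgcs1 (1.12 ± 0.20), Sc5d, Mvk and Cyp51 rose out of 25 (5 alone), with camera adjusted p = 0.214. Of 12 integrated stress response genes 1 rose and 0 fell (1 alone), with camera adjusted p = 0.275, and of 22 acute phase genes 0 rose and 2 fell (2 alone), with camera adjusted p = 0.468. Camera placed ribosome biogenesis (2 of 20 lower, Ncl and Polr1a; 3 alone), ribosomal proteins (0 of 24 called by edgeR) and nuclear-encoded oxidative phosphorylation (0 of 24) below other genes at adjusted p = 0.0130, 0.0298 and 0.00332, and at adjusted p = 0.657, 0.943 and 0.755 with an estimated correlation. Csf3r (0.87 ± 0.27) was called out of 2 neutrophil markers (2 alone), with camera adjusted p = 0.0386 and adjusted p = 0.353 with an estimated correlation. In total 1331 genes differed at ZT18, 697 higher and 634 lower in SL, with a median absolute log2 fold change of 0.56. The majority turned with DESeq2 (677 higher, 743 lower), with its size factors in edgeR (649 and 670), without a filter (508 and 631), without 4 libraries chosen after seeing the data (446 and 659) and without LL ZT12 replicate 3 (922 and 1058), among other settings.

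**Figure D5:**
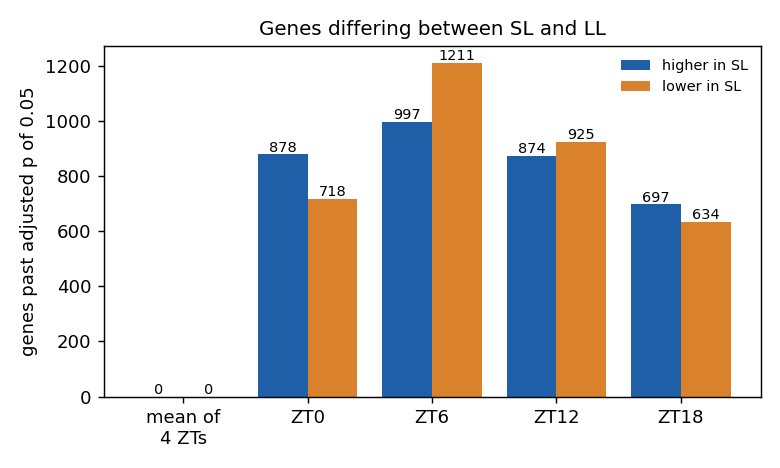
Number of genes (y axis) past an adjusted p of 0.05 for SL against LL as the mean of the 4 ZTs and at each ZT (x axis), with bars for genes higher and lower in SL. The bars for the mean of the 4 ZTs are at 0, and those for ZT6 at 997 and 1211.

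The last comparison averaged the SL minus LL difference over the 4 ZTs, which asks for a photoperiod effect that does not depend on the hour. With edgeR, 0 genes passed an adjusted p of 0.05. An unadjusted p under 0.05 was found in 730 of the 14456 tested genes, close to the share that chance alone gives at that threshold. DESeq2 called 6 genes, limma-voom 0 and limma on the authors' log2 values 0. Genes closest to the threshold, chosen after their values were seen, were Mup16 (1.43 ± 0.25) and Angptl2 (0.23 ± 0.04), both at edgeR adjusted p = 0.0547, then Mup18 (1.47 ± 0.30) and Mup11 (1.10 ± 0.23) at 0.139 and 0.150. Mup16, Mup18 and Mup11 belong to the major urinary protein family, whose copies are near-identical, so their reads are uncertain. DESeq2 called Angptl2, Mup11, Mup16, Mup18, Cyp2f2 and the muscle gene Myh1. Leaving out 1 library at a time gave 0 to 3 genes, the 3 being Mup16, Mup18 and Angptl2 without LL ZT12 replicate 3.

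No list had a called gene in the averaged comparison over all tested genes. Adjusted over the list alone, 1 gene passed in each of 4 lists, chosen here after their values were seen: Ier3 (-0.64 ± 0.17), Cyp2f2 (0.20 ± 0.05), Lrat (0.39 ± 0.09) and the muscle gene Mylpf (-1.29 ± 0.38). The metabolic genes with the highest CPM stayed near 0, with Scd1 at -0.03 ± 0.12, Pck1 at 0.08 ± 0.11 and Cyp2e1 at 0.01 ± 0.07. Camera placed 8 lists apart from other genes, with fatty acid oxidation (adjusted p = 0.00505), lipid droplet genes (0.0130) and endothelial markers (0.00237) higher in SL, and cold-inducible genes (0.0386), immediate early genes (0.0134), ribosomal proteins (7.92e-05), acute phase proteins (0.000269) and skeletal muscle markers (4.32e-07) lower. None held with an estimated correlation, where their adjusted p was 0.759, 0.507, 0.497, 0.275, 0.505, 0.718, 0.505 and 0.304 in that order. The median log2 difference was 0.06 for fatty acid oxidation and -2.90 for the muscle markers, of which Acta1 was at -2.29 ± 1.71.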

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

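The mislabelled library tests and the other splits of the samples were set before their results were seen. The common shift test was chosen after the shift between photoperiods had been seen, and all other tests here were chosen only after the result was seen. The rules for reading the mislabelled library test, the exchange test and both amplitude tests were also adjusted after their values were known, that of the core clock back to its first form.

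The photoperiod by ZT interaction was called in 4720 genes and a different 24 h rhythm in 5205 genes, so effects of photoperiod differed between times of day. The interaction had adjusted p = 1.87e-15 by edgeR for genes that included Por, Usp2, Ppard, Upp2, Cry1 and Tef, 2.608e-15 for Nrg4 and 4.413e-15 for Elovl3. Chance is unlikely for both counts, since the real labels ranked 1 of 100. The highest of the other splits gave 665 genes for the interaction and 609 for the rhythm. It is unlikely too for time of day in SL (2756 genes, highest other 307) and in LL (2650, highest other 1121), each ranked 1 of 100. Redrawn labels mix mice of different groups, which can lower their counts, and no rank below 1 of 100 is possible. Chance is therefore not excluded by these redraws. At each single ZT the real split was the 1 of 35 with the highest count. ZT0 gave 1596 genes (highest other 1) and ZT6 gave 2208 (highest other 42). ZT12 gave 1799 (highest other 453) and ZT18 gave 1331 (highest other 2). No rank below 1 of 35 is possible there, and no correction for several ZTs was made. The other splits also mix SL and LL mice within a group, which can lower their counts. Chance is thus unlikely at single ZTs but is not excluded by these splits. For the averaged effect the splits decide nothing, since the real count was 0 and each of 100 splits must give at least as many. The highest other gave 165. Labels redrawn unevenly within ZT can carry the differences at single ZTs into the average, so nothing is concluded from that count.

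The peak times about 10 h apart are the first pattern weighed. Once LL waves were moved by the clock median of -9.87 h, 0 of the 5205 genes kept a different rhythm. Of all 14456 tested genes, 455 (3.15%) then had an unadjusted p under 0.05. A common shift may therefore account for the rhythm differences that passed the threshold. It is not shown for all 24 h rhythms, because a gene not called after the move can still have another shift. Most of the 20 genes that fitted it worst were muscle genes with nearly equal peak times. Among them Atp2a1 had a shift of 0.1492 h and an edgeR adjusted p of 0.5855 once moved. None of the 20 was called, and time of day called 0 of 7 muscle markers in SL. At an unadjusted edgeR p under 0.05, 5 of 7 varied with time of day in SL, and 0 of 7 had an interaction. Muscle genes may thus be an exception to a common shift, which these values do not settle. The tables argue against single mislabelled libraries as the whole cause: 4 of 32 libraries lay nearer to another group, which met the number set beforehand, but the clock shift was -9.91 h (-11.2 to -8.65 h over 18 genes) in the other 28. An error of a whole sampling step alone would give -6 or -12 h, while the clock list gave -9.97 h with a jackknife SE of 0.312 h, 6.51 SE from -12 h; a step of 12 h together with a real difference near 2 h is not excluded. A hypothesis that stays open is that the livers follow another event of the light schedule than the one that sets ZT0, which could not be tested because the hours of light are not given in the sources used here.

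LL ZT12 replicate 3 is the second pattern, with a mean correlation to its group of 0.9686 against 0.9824 to 0.9837 for its mates. Exon length and the difference from its mates had a Spearman correlation of -0.435 across 12577 genes, which are not independent replicates, against -0.327 to 0.186 in 28 libraries of other groups, so fragmented RNA or a transcript length bias may contribute. Over the clock list its distance to its mates was 1.4 times that to SL ZT0, as a mislabelled time or photoperiod could give, although SL ZT0 replicate 3 (2.01), SL ZT12 replicate 2 (1.39) and LL ZT18 replicate 3 (1.04) met the same bound. An exchange of labels with SL ZT0 replicate 3 cannot be told apart from ordinary spread. Positions between the LL ZT12 (0) and SL ZT0 (1) means came from 16 fits, each without 1 library of each group. LL ZT12 replicate 3 lay at 0.459 in the fit without SL ZT0 replicate 3, and its mates ranged from 0.246 to 0.633 over their fits. SL ZT0 replicate 3 lay at 0.29 in the same fit, and at 0.369, 0.347 and 0.566 in its fits without LL ZT12 replicates 1, 2 and 4. The other SL ZT0 libraries ranged from 0.573 to 0.798. Its low position is therefore not particular to the pair with LL ZT12 replicate 3. Of the 200 genes used for the positions, 33 passed the threshold in the fit without both libraries. Nothing is concluded on an exchange. Another tissue cannot be told apart either: the highest median log2 difference of a marker list was 0.581 and rested on 3 gut epithelium genes.

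Skeletal muscle transcripts in some libraries are the third pattern. Over 32 libraries log2 Acta1 and the mean of the other 6 muscle markers had a Pearson r of 0.972 and a Spearman rho of 0.793, each with permutation p = 1e-05, the smallest that 100000 resamples can give, and r was 0.963 without the 2 libraries farthest from the median. Muscle attached to the liver piece would give this, but so would muscle genes switched on together in liver, and the 2 cannot be told apart by these values. A photoperiod difference of Acta1 at ZT18 had an exact permutation p of 0.171 over 70 splits, two-sided, with 4 mice per group, and stays open. The fitted waves of Acta1, Atp2a1, Myh1 and Mb peaked near 20 h in SL and LL (shifts of -0.6277, 0.1492, 0.2668 and -0.1842 h), unlike the clock genes. Larger shifts were fitted for the muscle genes Tcap (1.696 h) and Myh4 (1.647 h). All these genes were taken from the 20 that fitted the common shift worst, which favours a contrast with the clock genes. Acta1, Myh1 and Myh4 also belong to the list of 7 muscle markers fixed before the data were examined. In that list an unadjusted edgeR p under 0.05 was found for time of day in 5 of 7 genes in SL and 7 of 7 in LL. For the interaction it was found in 0 of 7. After adjustment over all genes, time of day called 0 of 7 muscle markers in SL, and neither explanation was tested on these waves.

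Single libraries far from their group were found in 26 of 310 tests of groups of 4, and LL ZT0 replicate 2 had 4 of them and LL ZT12 replicate 3 had 3. Chance would give about 15.5 for independent tests of normally distributed values. CPM values need not be so distributed, some genes were chosen for large fold changes, and genes of one library can deviate together. The excess over that number therefore decides nothing. In 3 of these tests the other 3 libraries of the group were at 0, which fixes the outcome, so they show nothing. They were Myh4 in SL ZT6 replicate 3 (0.09588 CPM) and LL ZT12 replicate 2 (0.06369 CPM) and Tcap in SL ZT6 replicate 4 (0.05073 CPM). Without them 23 of 307 tests remain, against about 15.35 under the same assumptions. Among muscle genes the others included Acta1 (29.09 CPM), Myh4 (7.081 CPM) and Tcap (3.394 CPM) in LL ZT0 replicate 2. Among clock genes these included Per2 in LL ZT0 replicate 3 (27.81 CPM), Tef in LL ZT0 replicate 1 (56.03 CPM), Hlf in LL ZT18 replicate 1 (102.3 CPM) and Bhlhe41 in LL ZT12 replicate 3 (2.843 CPM). Usp2 stood apart in SL ZT6 replicate 3 (32.26 CPM) and LL ZT6 replicate 1 (6.773 CPM), Cyp2a4 in SL ZT12 replicate 3 (2.654 CPM) and LL ZT6 replicate 2 (4.186 CPM), and Lmod2 in SL ZT18 replicate 4 (0.3725 CPM) and LL ZT18 replicate 3 (3.869 CPM). Gpr179 did so in SL ZT0 replicate 4 (7.463 CPM) and SL ZT18 replicate 3 (53.29 CPM), and Ppp1r3g in LL ZT6 replicate 4 (1.871 CPM) and LL ZT12 replicate 3 (8.618 CPM). Others were Mt2 in SL ZT0 replicate 2 (10.02 CPM), Slc34a2 in SL ZT0 replicate 4 (0.8502 CPM) and Elovl3 in SL ZT12 replicate 1 (734.1 CPM).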

How the results depend on the processing

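Tests chosen after seeing the data here are limma on the authors' log2 values, 4 libraries left out together (LL ZT12 replicate 3, LL ZT0 replicate 2, LL ZT18 replicates 2 and 3), LL taken later or moved in time, and every form of the median shift, the circular one included, which replaced the plain one between -18 and 6 h after its p was seen. The averaged effect, with 0 genes by edgeR, gave 9 without a filter on low counts, 6 with DESeq2, 2 without the 4 libraries, 1 with an additive model, and 0 to 3 with 1 library left out (3 without LL ZT12 replicate 3). Fitted on fewer samples, ZT12 gave 723 genes in place of 1799, and time of day 1655 in LL in place of 2650 and 3508 in SL in place of 2756. The interaction of 4720 genes was 1350, 75 and 3821 with LL taken 6, 12 and 18 h later, and the rhythm difference of 5205 was 0 with LL waves moved by the clock shift. Of 190 list tests camera called 60, and 0 with an estimated correlation. The median shift was -10.06 h (permutation p = 0.05) over genes called in both photoperiods and -9.534 h (permutation p = 0.06) as a plain median between -18 and 6 h. The cause of these changes was not tested.

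With 1 library left out, counts were 1115 to 2255 at ZT0, 1636 to 3053 at ZT6, 1316 to 2341 at ZT12, 975 to 1980 at ZT18, 4327 to 5651 for the interaction, 2312 to 3929 for time in SL, 2323 to 3152 for time in LL, 4870 to 6011 for the rhythm and 55 to 64 for the lists. The amplitude ratio ranged from 0.9752 to 1.072 and the shift from -9.705 to -9.397 h (highest permutation p = 0.03). The majority of higher or lower calls turned under some settings at ZT6, ZT12 and ZT18 and under none at ZT0. Without the 4 libraries the counts per ZT were 1893, 3083, 1673 and 1105, with a higher share at ZT18 of 40.4% in place of 52.4%. Of 413 named results, 374 passed their test, and 16914 alternative values had 16493 on the same side, 411 weaker, 10 stronger and 0 reversed. The replicate number as a block gave 1593, 2206, 1779 and 1310 genes per ZT, 4702 for the interaction, 2696 and 2636 for time of day, 5207 for the rhythm, 61 for the lists and 0 for the averaged effect. Libraries with the same number had a mean correlation of -0.0003 (-0.263 to 0.243), and 5 of 32 matched best with their own number. These correlations gave no sign that the numbers pair the mice. Replicate 4 had the lowest mitochondrial share of its group everywhere except in LL ZT12, for example 3.05% in LL ZT6 and 3.35% in LL ZT18. Its correlation of exon length with the difference from group mates was negative in the same groups, for example -0.327 in SL ZT18. A smaller effect tied to the replicate number is therefore not excluded.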

Other observations

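All tests of hypotheses here were chosen only after the result was seen.

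Other genes and lists gave these values. Among 20 growth hormone and male-biased genes, Elovl3 fell at ZT0 (-2.90 ± 0.23) and ZT6 (-1.75 ± 0.22) and rose at ZT12 and ZT18 (1.38 ± 0.22), and the steroid dehydrogenase gene Hsd3b5 fell at ZT6 (-1.49 ± 0.35) and rose at ZT18 (1.13 ± 0.34). Igf1, the gene of a growth factor released by liver, rose at ZT6 (0.36 ± 0.11) and fell at ZT18 (-0.37 ± 0.11), and Socs2, a feedback inhibitor gene of that axis, fell at ZT18 (-2.43 ± 0.64). The list had 2, 4, 2 and 4 called genes at ZT0, ZT6, ZT12 and ZT18 (3, 4, 2 and 6 adjusted over the list alone), and camera called it at no ZT (adjusted p = 0.684, 0.544, 0.743 and 0.873). Its interaction was called in 7 of 20 (7 alone). Of the 2 cold-inducible genes, Rbm3 rose at ZT0 (0.37 ± 0.10) and fell at ZT12 (-0.47 ± 0.10) and ZT18 (-0.40 ± 0.10), and Cirbp fell at ZT6 (-0.79 ± 0.15). The pericentral genes Slc1a4 (-1.56 ± 0.21), Lgr5 (-1.02 ± 0.22) and Axin2 (-0.64 ± 0.17), of which Lgr5 and Axin2 are Wnt targets, fell at ZT6 and rose at ZT18 (1.36, 1.42 and 1.13), with 4 and 3 of 12 called (4 and 3 alone).

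At ZT0, Pdk4, which codes for a kinase that limits glucose oxidation, fell by 2.10 on the log2 scale while the carnitine transferase gene Cpt1a rose (0.56 ± 0.12), and at ZT12 Pdk4 rose (1.95 ± 0.44) and Cpt1a fell (-0.54 ± 0.12). In that list of 26 fatty acid oxidation genes 3 rose and 2 fell at ZT0 (5 alone), and 1 rose and 2 fell at ZT12 (5 alone). Por (1.61 ± 0.17) and Cyp2a5 (1.29 ± 0.20) were among 5 of 23 xenobiotic genes that rose at ZT0, with 1 lower (7 alone). Among markers of other cells, Stab2 fell at ZT0 (-0.40 ± 0.09) and Bmp2 rose (0.40 ± 0.13), Cd9 fell at ZT6 (-0.87 ± 0.16) and rose at ZT18 (0.73 ± 0.17), and Sox9 rose at ZT12 (1.42 ± 0.23). No T and NK cell, B and plasma cell, erythroid, adipocyte or mesothelial marker was called by edgeR at any ZT over all genes, and adjusted over the list alone 1 B and plasma cell marker at ZT0 and 1 adipocyte marker at ZT6 were.

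The first hypothesis was that gene groups differ in how far they are shifted. Cholesterol synthesis genes called in both photoperiods (15 genes) had a mean shift 1.66 h less negative than the core clock list, with a jackknife SE over libraries of 0.789 h, and may be shifted less than the core clock. This was 1 of 14 lists beyond 2 SE and no correction for their number was made. Samples 6 h apart meet SL and LL waves at different phases. Waves that are not cosine-shaped could then give such a difference, which the jackknife does not measure. ER chaperone genes (13 genes) differed from the clock list by -1.51 h with an SE of 0.792 h, so whether they are shifted more stays open.

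The second hypothesis was that amplitudes are higher in SL. The core clock list had a mean log2 amplitude ratio of 0.196 with a jackknife SE of 0.09 (0.151 to 0.243 with 1 library left out), and its amplitude may be higher in SL. It was the 1 of 15 lists beyond 2 SE, and no correction for their number was made. Waves that are not cosine-shaped, sampled every 6 h at different phases in SL and LL, could also give such a ratio. The jackknife does not measure this. Fatty acid and triglyceride synthesis had a ratio of -0.256 with an SE of 0.282, which does not exceed 0 and leaves either direction open.

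In LL ZT12 replicate 3, genes chosen after their values were seen were Gpr179 at 287 CPM against a mean of 40.1 CPM in its mates, Hipk2 at 5.37 against 43.6 CPM, Ppara at 75.3 against 284 CPM and Mt1 at 69.4 against 14.7 CPM.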
